A study of Homo sapiens with 16 samples.

How the data were processed

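Polyadenylated RNA of HCT116 cells was sequenced in 16 strand-specific libraries. Per the labels, RNA was treated with DNase and depletion of NORAD by CRISPR interference was induced with doxycycline. The 6 groups, wild type and knockdown at 24 h, 48 h and 96 h, and the replicate numbers were taken from the sample titles. The deposited table holds estimated counts (expected counts) per transcript, written as whole numbers by the authors. All 18 values of 7 or more digits end in 0, so they were rounded before deposit. The submitters' processing notes name kallisto, DESeq2 and the build hg19, with no versions. The index, the filters and other settings are not given in the sources used here. kallisto divides reads that match several transcripts between them by a model, so counts of near-identical genes, pseudogenes and overlapping transcripts are uncertain.

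Of 166096 transcripts in the table, 156583 were matched by Ensembl identifier to GENCODE 29 (GRCh38) and 9513 were not. The unmatched transcripts held 2.75% to 3.40% of the counts of a library and were left out of library sizes and tests. The matched transcripts were summed to 31495 genes and rounded, and all coordinates are those of GENCODE 29 on GRCh38. Library totals lay between 28391784 and 51853876 estimated counts. At that depth and with 2 or 3 libraries per group, precision is set by the spread between libraries more than by counting. Intervals or floors from counts cover counting error only. Replicate pairs differed by more than sampling noise (chi-square over degrees of freedom from 7.84 to 55.9), so no pair was treated as the same library.

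Genes were tested with edgeR 4.0.16 in R 4.3.3 on the estimated counts. filterByExpr on the 6 groups left 19836 genes and libraries were scaled by the trimmed mean of M-values (TMM). A model with a mean per group over all 16 libraries (10 residual degrees of freedom) was fitted with glmQLFit (robust) and tested with glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum fold change. The contrasts were knockdown minus wild type at each time, the mean of these 3 differences, an F test of their difference between times, 96 h minus 48 h, the mean of 48 h and 96 h, that mean minus 24 h, and wild type at 96 h minus 24 h. Log2 fold changes are edgeR's, SEs come from the same fit, and CPM values use TMM library sizes. For genes at 0 in a whole group a fold was computed against a floor of 3 counts over that group.

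The genes named were chosen by rule: NORAD, and for each knockdown contrast the 10 largest rises and 10 largest falls among genes that passed, had a mean CPM of at least 5 and had every knockdown library on the same side of every wild-type library of its time (5 and 5 for wild type over time). From each fixed gene list, up to 4 members with the lowest p at that time were eligible, as was any passing member of the lists of complex components, Pumilio and partner genes, topoisomerases and NORAD neighbours. For transcript usage the rule took the 5 genes with the lowest p per contrast. Some genes that the rule gives are not reported here. RIC8A and IL23R fall outside it and were chosen after their values were seen. The design, the named-gene rule, the gene lists and most of the other settings tried were fixed before the data were examined.

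Gene lists written from general knowledge held 782 symbols, of which 730 matched. The 28 lists with at least 4 tested members were tested with limma 3.58.1 camera (preset correlation 0.01) on edgeR log-CPM and adjusted over 84 tests, with camera under an estimated correlation and fry beside it. The lists covered NORAD's neighbours, the complex components, Pumilio and partner genes, Pumilio-repressed genes, topoisomerases, p53 targets, DNA replication, mitosis, cohesin and condensin, DNA repair, interferon, stress responses, sterol synthesis, hypoxia and glycolysis, beta-catenin targets, intestinal differentiation, adhesion, immediate early genes, NF-kappaB targets, mitochondrially encoded RNAs, histones, ribosomal proteins, ribosome biogenesis, the respiratory chain, splicing factors, lncRNAs and markers of other cells. For the Pumilio motif, 3' UTRs of at least 20 bases of 17926 genes were searched for UGUANAUA and genes with and without it were compared by camera.

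Transcript usage was tested with edgeR's diffSpliceDGE (Simes) on 12784 genes. An added test used limma on the log ratio of each transcript to the rest of its gene, with 0.5 counts added, for transcripts with at least 10% of their gene in a group (10258 genes). Each test was run first on independent counts simulated from the real means with 200 or 400 changed genes. The edgeR gene test found 48%, 59% and 63% of the genes changed 1.5-fold and 76%, 91% and 90% of those changed 2-fold at 24 h, 48 h and 96 h, with 3.88%, 4.76% and 6.13% of calls false. In the average 85% and 98% were found (4.84% false), and for the difference between times 34% and 80% (5.0% false). The list test found 5 of 5 shifted lists at each time and 0 of 5 unshifted. Its preset correlation was thus not tested. The edgeR usage test found 55%, 73%, 69% and 92.5% of changed genes (24 h, 48 h, 96 h, average). The share test found 59%, 66.5%, 68% and 77.5%. The results give their false calls.

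The other settings fixed in advance were DESeq2's size factors, DESeq2 1.42.0, limma-voom, no filter, a filter at a CPM of 5 in 2 libraries, a replicate block, each library left out in turn, only the libraries of the time tested, a transcript-level test, glmTreat against a 1.2-fold change. Lists were also tested with an estimated correlation and fry, the motif with at least 2 copies, as UGUAHAUA and with 3' UTR length as a covariate, and usage with limma diffSplice and with transcripts of at least 10% of their gene. Added after the data were seen were total-count, upper-quartile and abundance-dependent scaling (a loess of each library on mean expression, span 0.3), leaving out transcripts that hold a run of 31 or more A or T (159 transcripts of 136 genes), leaving out knockdown replicates 1 and 2 of 48 h together, covariates for 3' UTR length and GC content together, a reversed control motif, and the share test. DESeq2 gave no adjusted p for 5396 genes at 24 h, 2322 at 48 h and 5781 at 96 h. Principal components used log2 CPM. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 did the remaining steps. The reads were not used, so splicing was seen only as the authors' estimated counts per annotated transcript.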

Results

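The series measured polyadenylated RNA by strand-specific sequencing in HCT116, a human colon cancer cell line, with and without depletion of the long noncoding RNA NORAD. Depletion was by CRISPR interference, in which a catalytically dead Cas9 carrying a repressor is directed to a promoter, and was induced with doxycycline. The stated purpose was to find changes of gene expression and of alternative splicing in NORAD-depleted cells. There were 16 libraries in 6 groups, with 2 wild-type and 2 knockdown libraries at 24 h, 3 and 3 at 48 h, and 3 and 3 at 96 h. The total estimated count per library lay between 28391784 and 51853876. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. In a principal component analysis of log2 CPM (counts relative to library size), component 1 held 35.1% and component 2 held 23.8% of the variance. Component 1 separated the 3 times, and component 2 set 96 h apart from 24 h and 48 h, which overlapped on it. Component 3 (11.3%) set most knockdown libraries apart from the wild-type libraries of their time. Knockdown replicate 3 at 48 h scored 7.94 on it against -54.2 and -61.2 for its replicates 1 and 2. Adjusted p-values of single genes below are from edgeR's quasi-likelihood test over 19836 genes with Benjamini-Hochberg adjustment. Those of gene lists are from limma's camera, adjusted over 84 tests.

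NORAD (ENSG00000260032, annotated as a lincRNA at chr20:36045622-36050960 on the minus strand, GRCh38) was strongly lower in the knockdown libraries at 48 h and 96 h and not at 24 h. Mean CPM was 157.8 ± 3.99 (SD, n = 3) in wild type and 21.5 ± 3.34 (n = 3) in knockdown at 48 h, which is 13.6% of wild type. At 96 h it was 182.8 ± 1.37 (n = 3) and 72.9 ± 6.86 (n = 3), 39.9% of wild type. At 24 h it was 190.0 ± 15.9 (n = 2) and 208.7 ± 29.7 (n = 2), 109.8% of wild type. The log2 fold changes were -2.88 (SE 0.105, edgeR adjusted p = 1.27e-13) at 48 h, -1.33 (SE 0.098, edgeR adjusted p = 5.25e-08) at 96 h and 0.14 (SE 0.117, edgeR adjusted p = 0.523) at 24 h. The effect differed between times (edgeR interaction adjusted p = 8.28e-10). Under total-count scaling NORAD passed as higher at 24 h (log2 fold change 0.34, edgeR adjusted p = 0.0465). Because the target was not lower at 24 h, those libraries are called libraries labelled knockdown, and any direction at 24 h is that of the labels.

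**Figure D1:**
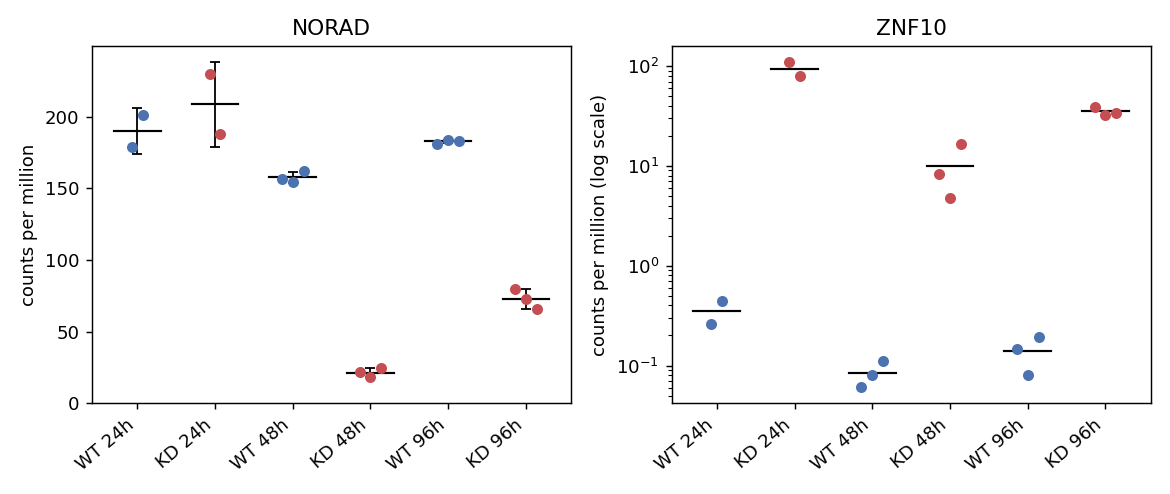
CPM of NORAD (left, linear axis) and ZNF10 (right, log axis) in the 16 libraries, grouped by label (WT wild type, KD knockdown) and time, with a point per library, horizontal lines at group means and, for NORAD, error bars of 1 SD. NORAD fell from a mean of 157.8 to 21.5 CPM at 48 h and from 182.8 to 72.9 CPM at 96 h. ZNF10 lay between 4.72 and 109.5 CPM in the knockdown libraries, those of 24 h included, and between 0.0607 and 0.439 CPM in the wild-type libraries.

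At 24 h the libraries labelled knockdown had higher RNA of most tested interferon-stimulated genes and lower RNA of most tested genes for ribosome production, DNA replication, mitosis and sterol synthesis. With an estimated correlation in camera, the interferon list alone passed at 24 h, and the lists that fell did not (adjusted p = 0.0553 for ribosome biogenesis, 0.265 for ribosomal proteins, 0.153 for DNA replication and 0.171 for both mitosis and sterol genes). The largest rise was of ZNF10, a KRAB zinc-finger gene (ENSG00000256223, chr12:133130575-133159465, plus strand, GRCh38), from 0.351 ± 0.124 to 94.1 ± 21.7 CPM (SD, n = 2 and 2; log2 fold change 8.05, SE 0.661, edgeR adjusted p = 2.69e-05). Whether the ZNF10 reads come from the gene itself or from the repressor of the CRISPR interference could not be told. The next largest rise was of CEMIP (ENSG00000103888, chr15:80779343-80951776, plus strand), which binds hyaluronan (4.50, SE 0.203, edgeR adjusted p = 1.54e-10). The interferon-stimulated IFIT1, OAS1, IFI6 and DDX58 rose by log2 fold changes of 2.89, 2.65, 2.60 and 2.03. The other large rises were of ZNF608 (2.33), PARP10 (1.90), CARNS1 (1.69) and ZDHHC17 (1.54). The largest falls were of CEP83, a centriole appendage gene (-4.30, SE 0.219, edgeR adjusted p = 3.71e-11), the potassium channel gene KCNK1 (-3.90), the ephrin receptor gene EPHB2 (-3.83) and FKBP10, an endoplasmic reticulum prolyl isomerase (-2.89). PLEKHH2 (-1.91), ZFHX4 (-1.76), IL32 (-1.72), XAB2 (-1.56), LINC00678 (-1.55) and MARC1 (-1.50) fell as well. In all, 3484 genes passed, 1019 rising and 2465 falling. Of these, 203 rose and 74 fell at least to the log2 change of a doubling.

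Of the 35 tested interferon-stimulated genes, 27 rose at 24 h and 8 did not pass (31 rose adjusted over the list alone; median log2 fold change 1.02), with IFIT3 at 1.97 (SE 0.206). The list passed (camera adjusted p = 2.36e-28), also with an estimated correlation (adjusted p = 1.48e-04). Among 27 ribosome biogenesis and MYC-driven genes 25 fell, both over all genes and adjusted over the list alone, with the nucleolar methyltransferase gene FBL at -1.01, TCOF1 at -0.89 and MYC at -1.12. The list passed (camera adjusted p = 3.96e-19; adjusted p = 0.0553 with an estimated correlation). Of 79 cytosolic ribosomal protein genes 76 fell (78 adjusted over the list alone), RPL14 by -0.68. The list passed (camera adjusted p = 9.00e-28; adjusted p = 0.265 with an estimated correlation). Mitosis genes fell in 37 of 46 cases (46 adjusted over the list alone), among them UBE2C (-0.74), the cyclin gene CCNB1 (-0.67) and the kinase gene AURKB (-0.57). The mitosis list passed (camera adjusted p = 3.32e-17; adjusted p = 0.171 with an estimated correlation). DNA replication genes fell in 38 of 44 cases (40 adjusted over the list alone), with POLD2 at -0.56 and the helicase subunit gene MCM7 at -0.54. The list passed (camera adjusted p = 2.02e-16; adjusted p = 0.153 with an estimated correlation). DNA repair genes fell in 14 of 37 cases (17 adjusted over the list alone), EXO1 by -0.64. The list passed (camera adjusted p = 4.52e-06; adjusted p = 0.265 with an estimated correlation). Of 22 cohesin and condensin genes 13 fell (16 adjusted over the list alone), the condensin gene NCAPG by -0.60. The 1 that rose was the cohesin loader gene MAU2 (0.42), chosen after its value was seen. The list passed (camera adjusted p = 1.63e-05; adjusted p = 0.265 with an estimated correlation). These directions, and those of the lists that follow for 24 h, kept their sign as medians under each scaling, but under total-count scaling the members that fell numbered 13 for mitosis, 12 for DNA replication, 33 for ribosomal proteins and 19 for ribosome biogenesis. Under abundance-dependent scaling 5 of the 79 ribosomal protein genes fell, and their median was -0.06 against -0.43 under TMM (camera adjusted p = 0.0314).

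Sterol synthesis and uptake genes fell at 24 h in 17 of 23 cases, with the same count adjusted over the list alone, among them INSIG1 (-1.04), ACAT2 (-0.92) and FDPS (-0.62). The sterol list passed (camera adjusted p = 2.70e-11; adjusted p = 0.171 with an estimated correlation). Of 30 genes of the integrated stress and unfolded protein responses 19 fell (19 adjusted over the list alone), including the asparagine synthetase gene ASNS (-0.74) and CHAC1 (-1.01). The stress response list passed (camera adjusted p = 6.23e-09; adjusted p = 0.244 with an estimated correlation). Nuclear-encoded respiratory chain genes fell in 23 of 41 cases (32 adjusted over the list alone), NDUFA10 by -0.49. The list passed (camera adjusted p = 6.26e-11; adjusted p = 0.265 with an estimated correlation). Under abundance-dependent scaling 8 of the 41 fell and 1 rose, and their median was -0.09 against -0.32 under TMM. Of 34 SR protein and hnRNP genes 18 fell (21 adjusted over the list alone), HNRNPA1 by -0.57. RBM5 rose (0.35) and was chosen after its value was seen. The list passed (camera adjusted p = 1.30e-06; adjusted p = 0.322 with an estimated correlation). Under abundance-dependent scaling 0 of these 34 fell and 2 rose, and the list no longer passed (median -0.07 against -0.32 under TMM, camera adjusted p = 0.491). Among 21 immediate early genes 9 fell (12 fell and 1 rose adjusted over the list alone). The immediate early list passed (camera adjusted p = 2.18e-04; adjusted p = 0.465 with an estimated correlation). The glycolytic ENO1 (-0.51), ALDOA (-0.58) and LDHA (-0.50) and the mitophagy receptor gene BNIP3 (-0.39) were the 4 of 25 hypoxia and glycolysis genes that fell (3 adjusted over the list alone). The hypoxia list passed (camera adjusted p = 0.0036; adjusted p = 0.702 with an estimated correlation, and 0.114 under abundance-dependent scaling). Of 19 replication-dependent histone genes, whose RNAs mostly lack a poly(A) tail, HIST1H4C fell (-0.93; not past the threshold adjusted over the list alone) and 18 did not pass. The histone list passed (camera adjusted p = 0.0295; adjusted p = 0.735 with an estimated correlation). Without wild-type replicate 1 or knockdown replicate 2 at 24 h the histone list no longer passed (camera adjusted p = 0.668 and 0.12). Without knockdown replicate 2 the hypoxia list changed its direction (camera adjusted p = 0.99).

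The series names a topoisomerase complex in its title, and its listed components are TOP1, RBMX and the PRP19 complex of the spliceosome. Of 14 tested components 7 fell at 24 h (9 adjusted over the list alone) and 7 did not pass. Those that fell were XAB2 (-1.56), ISY1 (-0.57), the topoisomerase gene TOP1 (-0.52, SE 0.084, edgeR adjusted p = 2.17e-04), the ubiquitin ligase gene PRPF19 (-0.50), CTNNBL1 (-0.43), the RNA-binding RBMX (-0.33) and SYF2 (-0.32). The list passed (camera adjusted p = 7.70e-05; adjusted p = 0.178 with an estimated correlation). Of 10 topoisomerase and adduct repair genes 6 fell (7 adjusted over the list alone), namely TOP1, the mitochondrial TOP1MT (-0.49), TOP2A (-0.41), the DNA adduct hydrolase gene TDP1 (-0.36), TOP3A (-0.31) and PARP1 (-0.29). The topoisomerase list passed (camera adjusted p = 0.00659; adjusted p = 0.0808 with an estimated correlation, and 0.14 under abundance-dependent scaling). Several of these calls rested on single libraries. Without wild-type replicate 1, wild-type replicate 2, knockdown replicate 1 or knockdown replicate 2 of 24 h, RBMX (edgeR adjusted p = 0.0626, 0.198, 0.0997 and 0.276), SYF2 (0.131, 0.182, 0.0924 and 0.388), TDP1 (0.079, 0.194, 0.173 and 0.171), TOP3A (0.116, 0.169, 0.119 and 0.301) and PARP1 (0.131, 0.247, 0.219 and 0.288) did not pass. They did not pass without wild-type replicate 2 of 48 h either (RBMX 0.0813, SYF2 0.0932, TDP1 0.0779, TOP3A 0.0937 and PARP1 0.139). SYF2 and PARP1 were lost without other libraries of 48 h and 96 h (0.0504 to 0.0601), as was TOP2A without wild-type or knockdown replicate 2 of 24 h (0.0553 and 0.0885). They also rested on the scaling. Under total-count, upper-quartile and abundance-dependent scaling RBMX (edgeR adjusted p = 0.397, 0.0647 and 0.391), SYF2 (0.52, 0.252 and 0.275), TOP2A (0.183, 0.0502 and 0.195), TOP3A (0.55, 0.168 and 0.157) and PARP1 (0.586, 0.147 and 0.778) did not pass. TDP1 did not pass under the first and second of these (0.423 and 0.122), and CTNNBL1 (0.0738) and TOP1MT (0.0708) not under total-count scaling. XAB2, ISY1, TOP1 and PRPF19 passed under each of the 3 scalings, but XAB2 did not pass with only the libraries of 24 h in the fit (log2 fold change -1.50, edgeR adjusted p = 0.225), nor PRPF19 against a 1.2-fold change by glmTreat (0.0544).

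The 24 h count of 3484 genes depended on single libraries, with 1500 without knockdown replicate 2, 1732 without wild-type replicate 2, 1945 without knockdown replicate 1 and 2084 without wild-type replicate 1. The division into rises and falls depended on the scaling: 29.2% of called genes rose under TMM, 75.4% (2477 rose and 810 fell) under total-count scaling, 53.7% under upper-quartile scaling and 49.2% under abundance-dependent scaling. Total-count and upper-quartile scaling shifted the median of all genes by 0.21 and 0.11 log2. The share of counts in transcripts annotated as retained introns was 5.58% and 6.04% in the libraries labelled knockdown and 5.17% and 4.93% in wild type, and mitochondrially encoded genes held 5.87% and 5.89% in the libraries labelled knockdown and 4.74% and 4.89% in wild type. Both differences lie beside each gene group above. Calls that ended without a library of 24 h were ZDHHC17 (edgeR adjusted p = 0.134, 0.0759, 0.096 and 0.0565 without wild-type replicates 1 and 2 and knockdown replicates 1 and 2) and ZFHX4 (0.123 without wild-type replicate 2 and 0.14 without knockdown replicate 1). So did IL32 (0.136 without wild-type replicate 1 and 0.159 without knockdown replicate 2), LDHA (0.0573, 0.0567 and 0.322 without wild-type replicates 1 and 2 and knockdown replicate 2) and ALDOA (0.0878 and 0.219 without wild-type replicate 1 and knockdown replicate 2). ENO1 was lost without knockdown replicate 2 (0.114). MAU2 was lost without wild-type replicate 1 (0.0955) or knockdown replicate 2 (0.0873), and HIST1H4C without each library of 24 h (0.0506 to 0.283) and wild-type replicate 2 of 48 h (0.0577). BNIP3, at an edgeR adjusted p of 0.0499, was lost without any of 12 of the 16 libraries (0.0547 to 0.674), that is, all but knockdown replicate 1 of 24 h, knockdown replicates 2 and 3 of 48 h and wild-type replicate 3 of 96 h. By the scaling, LDHA (0.0667 and 0.361) and BNIP3 (0.344 and 0.168) were lost under total-count and abundance-dependent scaling, HIST1H4C under total-count and upper-quartile scaling (0.0969 and 0.103), and ENO1 (0.751), ALDOA (0.463) and HNRNPA1 (0.144) under abundance-dependent scaling. BNIP3 was lost under upper-quartile scaling as well (0.132). With only the libraries of 24 h in the fit, ZFHX4 (0.0914), IL32 (0.337), GDF15 (0.167), ALDOA (0.163) and BNIP3 (0.118) did not pass.

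At 48 h NORAD was at 13.6% of wild type. Under TMM the knockdown libraries had lower RNA of most tested ribosome biogenesis, DNA replication and splicing genes, the last by less under abundance-dependent scaling. They had higher RNA of ZNF10, CEMIP and some interferon-stimulated genes. No list passed at 48 h with an estimated correlation in camera (adjusted p = 0.0548 for ribosome biogenesis, 0.263 for DNA replication, 0.265 for SR and hnRNP genes and 0.0641 for interferon-stimulated genes; 2 lists had an unadjusted p under 0.05, and fry passed 16). ZNF10 went from 0.084 ± 0.0249 to 9.92 ± 6.13 CPM (SD, n = 3 and 3; log2 fold change 6.80, SE 0.711, edgeR adjusted p = 3.98e-05). CEMIP rose by 3.56 (SE 0.160, edgeR adjusted p = 8.97e-11). Further rises were of the antisense gene AC006064.4 (2.43), the integrin gene ITGAX (2.28), SPTSSB (2.13), ZNF608 (1.85), TRIML2 (1.82), the kinetochore gene CENPT (1.71) and the interferon regulatory factor gene IRF7 (1.63). The largest falls after NORAD were of the keratin gene KRT6A (-2.48), the vitamin D hydroxylase gene CYP24A1 (-2.40, SE 0.088, edgeR adjusted p = 1.27e-13), KIDINS220 (-2.27), KCNK1 (-2.15), CEP83 (-2.10), CPA4 (-1.995), KRT13 (-1.92), FKBP10 (-1.85) and WNT16 (-1.81). In all, 6591 genes passed, 2928 rising and 3663 falling. Of them 855 rose and 136 fell at least to a doubling or its inverse.

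All 27 tested ribosome biogenesis and MYC-driven genes fell at 48 h, also adjusted over the list alone and, in 26 cases, under total-count scaling, with RRS1 at -1.03, the nucleolin gene NCL at -0.92 and MYC at -1.74. The list passed (camera adjusted p = 3.02e-20; adjusted p = 0.0548 with an estimated correlation). DNA replication genes fell in 32 of 44 cases (34 adjusted over the list alone), with the sliding clamp gene PCNA at -0.64 and MCM6 at -0.60. The list passed (camera adjusted p = 8.26e-11; adjusted p = 0.263 with an estimated correlation). Of 34 SR protein and hnRNP genes 23 fell (27 adjusted over the list alone), SRSF1 by -0.58 and RBMX by -0.59. The 2 that rose were RBM5 (0.22) and CLK1 (0.24), named after their values were seen. The SR and hnRNP list passed (camera adjusted p = 5.40e-08; adjusted p = 0.265 with an estimated correlation). Of 35 interferon-stimulated genes 15 rose (16 adjusted over the list alone), IFI6 by 1.24 and STAT2 by 0.79. OAS1 fell (-0.61; named after its value was seen) and 19 did not pass. The interferon list passed (camera adjusted p = 2.27e-04; adjusted p = 0.0641 with an estimated correlation). Ribosomal protein genes fell in 52 of 79 cases (64 adjusted over the list alone), RPL22 by -0.43. The list passed (camera adjusted p = 2.17e-13; adjusted p = 0.465 with an estimated correlation). Under abundance-dependent scaling it did not pass, its direction by camera turned (camera adjusted p = 0.936) and 0 of the 79 fell, and RPL22 did not pass (edgeR adjusted p = 0.0514). Nuclear-encoded respiratory chain genes fell in 14 of 41 cases (14 adjusted over the list alone), SDHD by -0.63. UQCRFS1 rose (0.33; named after its value was seen). The list passed (camera adjusted p = 6.66e-04; adjusted p = 0.583 with an estimated correlation). Their median of -0.13 turned to 0.00 under total-count scaling and to 0.05 under abundance-dependent scaling (camera adjusted p = 0.678).

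Fewer members of the mitosis list passed at 48 h. Of 46, 17 fell (18 adjusted over the list alone), CCNA2 by -0.48 and CCNB1 by -0.42. The 2 that rose were CDC25C (0.48) and CENPE (0.35), named after their values were seen. The mitosis list passed (camera adjusted p = 6.66e-04; adjusted p = 0.584 with an estimated correlation, and 0.582 under abundance-dependent scaling). DNA repair genes fell in 11 of 37 cases (12 adjusted over the list alone), EXO1 by -0.57. The kinase gene ATM rose (0.33; named after its value was seen). The DNA repair list passed (camera adjusted p = 6.66e-04; adjusted p = 0.465 with an estimated correlation). Sterol genes fell in 8 of 23 cases (8 adjusted over the list alone), the squalene epoxidase gene SQLE by -0.77. STARD4 rose (0.29; named after its value was seen). The sterol list passed (camera adjusted p = 0.0149; adjusted p = 0.623 with an estimated correlation, 0.734 under abundance-dependent scaling and 0.0666 without knockdown replicate 1 of 48 h). Direct p53 target genes moved in both directions: 13 of 38 fell, among them PTP4A1 (-1.88) and TRIAP1 (-0.79). Among the 5 that rose were TRIM22 (1.08), TP53I3 (0.69), TP53INP1 (0.47) and the cyclin-dependent kinase inhibitor gene CDKN1A (0.41), named after their values were seen (14 fell and 5 rose adjusted over the list alone). The p53 target list passed (camera adjusted p = 0.0182; adjusted p = 0.523 with an estimated correlation, and 0.325 under abundance-dependent scaling). Of the 14 listed complex components 6 fell (6 adjusted over the list alone), RBMX, PRPF19 (-0.47), PLRG1 (-0.29), ISY1 (-0.27), BCAS2 (-0.22) and CTNNBL1 (-0.19). The list passed (camera adjusted p = 0.00896; adjusted p = 0.358 with an estimated correlation, and 0.26 under abundance-dependent scaling). TOP1MT (-0.43), TOP2B (-0.32) and TDP1 (-0.30) were the 3 of 10 topoisomerase genes that fell (3 adjusted over the list alone; camera adjusted p = 0.14). Under total-count, upper-quartile and abundance-dependent scaling PLRG1 (edgeR adjusted p = 0.117, 0.0546 and 0.102), ISY1 (0.142, 0.0968 and 0.0974), BCAS2 (0.44, 0.269 and 0.268), CTNNBL1 (0.589, 0.424 and 0.591) and TOP2B (0.297, 0.257 and 0.39) did not pass, nor did TDP1 under the first and second of them (0.194 and 0.0906). The median of that list, -0.14, turned to 0.02 under abundance-dependent scaling. In 13 further lists without a call (camera adjusted p from 0.105 to 0.746) 25 of 216 members rose and 39 fell, among them the immediate early genes EGR3 (1.41) and EGR1 (1.18), which rose, and the intestinal differentiation genes KRT20 (-1.73) and CDX2 (-0.51), which fell.

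Without knockdown replicates 1 and 2 of 48 h together, the libraries with the highest retained-intron shares (5.73% and 5.29%, against 4.18% in replicate 3 and 4.05% to 4.26% in wild type), 3990 genes passed at 48 h. Mitochondrially encoded genes held 11.9% to 13.4% of the counts in the 3 knockdown libraries of 48 h and 10.1% to 10.8% in wild type, a difference that lies beside each gene group of 48 h. AC006064.4 (edgeR adjusted p = 0.408), KIDINS220 (0.132), CCNA2 (0.0563), CDX2 (0.0839), OAS1 (0.637), CENPE (0.799), ATM (0.492), TRIM22 (0.925), CLK1 (0.465), PLRG1 (0.381), BCAS2 (0.508), CTNNBL1 (0.283), TDP1 (0.257), TOP2B (0.0948) and RBM12 (0.0937) did not pass without those replicates. The share of called genes that rose was 44.4% under TMM, 68.9% (4731 rose and 2134 fell) under total-count scaling and 64.3% under upper-quartile scaling, which shifted the median of all genes by 0.14 and 0.12 log2. Leaving out 1 library of 48 h at a time ended the calls of CENPE, CLK1 and BCAS2 without knockdown replicates 1 and 2 and wild-type replicates 1 and 2, and of CLK1 and BCAS2 also without wild-type replicate 3 (edgeR adjusted p up to 0.143, 0.141 and 0.153). The same applied to CTNNBL1 without knockdown replicates 1 and 2 and wild-type replicates 1 and 2 (0.152, 0.0518, 0.16 and 0.143), to STARD4 without knockdown replicates 1 and 3 and wild-type replicates 1 and 2 (0.0766, 0.139, 0.172 and 0.0965) and to ATM without knockdown replicate 1 and wild-type replicates 1 and 2 (0.135, 0.066 and 0.0682). It also ended those of OAS1 (0.0673, 0.079 and 0.0544 without knockdown replicates 1 and 2 and wild-type replicate 1), TRIM22 (0.0563, 0.0643 and 0.0532 without knockdown replicate 2 and wild-type replicates 1 and 2). TOP2B (0.0884, 0.126, 0.0742 and 0.123 without knockdown replicates 2 and 3 and wild-type replicates 1 and 3), TDP1 (0.0827 and 0.0513 without knockdown and wild-type replicate 2), PLRG1 (0.0762 and 0.056 without knockdown and wild-type replicate 1) and RBM5 (0.0565 without wild-type replicate 1). BCAS2, CTNNBL1 and STARD4 were lost without single libraries of 24 h and 96 h as well (0.0501 to 0.0599). With only the libraries of 48 h in the fit, AC006064.4 (0.132), PLRG1 (0.0518), BCAS2 (0.104), CTNNBL1 (0.158), TDP1 (0.0772), OAS1 (0.155), CENPE (0.068), ATM (0.0645), STARD4 (0.0694), CLK1 (0.0556) and TRIM22 (0.105) did not pass.

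At 96 h, with NORAD at 39.9% of wild type, the clearest change was a fall of mitosis genes, beside a fall of DNA replication genes whose list did not pass with an estimated correlation (camera adjusted p = 0.0548). Some interferon-stimulated genes (11 of 35) and adhesion genes (8 of 22) rose. All 46 tested mitosis genes fell (46 adjusted over the list alone; median log2 fold change -0.79 under TMM, -0.77 to -0.79 under each other scaling), among them CCNB1 (-0.95), UBE2C (-0.84) and AURKB (-0.78). The mitosis list passed (camera adjusted p = 2.76e-54; adjusted p = 0.0256 with an estimated correlation). HMMR (-1.08, SE 0.10, edgeR adjusted p = 6.18e-07), CENPF (-0.98), MDC1 (-1.06) and FAM72D (-1.04) were among the 10 largest falls, with CEP83 (-1.64), SCGB3A2 (-1.23), the antisense genes AL392023.2 (-1.16) and AP000446.1 (-0.997) and the lincRNA AC009055.2 (-1.03). Among the largest rises were ZNF10 (7.98, SE 0.576, edgeR adjusted p = 9.58e-06; 0.14 ± 0.0562 to 35.3 ± 3.57 CPM, n = 3 and 3), CEMIP (3.70), SHC2 (1.39), RCOR1 (1.34), the glycosyltransferase gene GALNT5 (1.32), ITGAX (1.19), ECM1 (1.15), CLIC3 (1.05) and the interferon-induced IFITM3 (1.04). In all, 2083 genes passed, 1062 rising and 1021 falling. Of those genes 56 rose and 28 fell at least to a doubling or its inverse.

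DNA replication genes fell at 96 h in 39 of 44 cases (42 adjusted over the list alone), with the polymerase subunit gene POLA1 at -0.74 and CDC45 at -0.68. The list passed (camera adjusted p = 9.20e-33; adjusted p = 0.0548 with an estimated correlation). DNA repair genes fell in 20 of 37 cases (26 adjusted over the list alone), RAD54L by -0.80 and FANCD2 by -0.62 (camera adjusted p = 7.22e-17; adjusted p = 0.0641 with an estimated correlation). Cohesin and condensin genes fell in 15 of 22 cases (18 fell and 1 rose adjusted over the list alone), NCAPG by -0.93 and the shugoshin gene SGO2 by -0.92. The list passed (camera adjusted p = 2.61e-12; adjusted p = 0.0808 with an estimated correlation). TOP2A (-0.98), TDP1 (-0.34) and PARP1 (-0.27) were the 3 of 10 topoisomerase genes that fell (3 adjusted over the list alone). The list passed (camera adjusted p = 0.00659; adjusted p = 0.0808 with an estimated correlation). Of 35 interferon-stimulated genes 11 rose (16 adjusted over the list alone), IFI6 by 0.85 and OASL by 0.76, and 24 did not pass. The interferon list passed (camera adjusted p = 6.26e-11; adjusted p = 0.00614 with an estimated correlation). Of 22 epithelial-mesenchymal and adhesion genes 8 rose (11 adjusted over the list alone), including the tight junction genes CLDN3 (0.89) and CLDN4 (0.57). The epithelial splicing regulator gene ESRP1 fell (-0.29; named after its value was seen). The list passed (camera adjusted p = 1.93e-06; adjusted p = 0.265 with an estimated correlation). Ribosome biogenesis genes fell in 11 of 27 cases, FBL by -0.47 and NPM1 by -0.51 (14 adjusted over the list alone; camera adjusted p = 1.27e-08; adjusted p = 0.195 with an estimated correlation). So did 11 of 34 SR protein and hnRNP genes, HNRNPM by -0.47 and SRSF1 by -0.40 (13 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.30e-06; adjusted p = 0.322 with an estimated correlation). Of 23 sterol genes 7 fell, ACAT2 by -0.49 (8 adjusted over the list alone). The sterol list passed (camera adjusted p = 4.85e-04; adjusted p = 0.465 with an estimated correlation). LDHA (-0.60), PDK1 (-0.43), BNIP3 (-0.36) and ENO1 (-0.28) were the 4 of 25 hypoxia and glycolysis genes that fell (7 fell and 1 rose adjusted over the list alone). The hypoxia list passed (camera adjusted p = 0.0213; adjusted p = 0.745 with an estimated correlation). The ribosomal protein list passed with a median of only -0.06 (camera adjusted p = 0.0318; adjusted p = 0.812 with an estimated correlation, and 0.324 under abundance-dependent scaling). The complex components did not pass (median -0.14, camera adjusted p = 0.0686; 0.0423 under abundance-dependent scaling, 0.046 without knockdown replicate 1 of 96 h and 0.0447 without knockdown replicate 3 of 48 h). In 12 further lists without a call (camera adjusted p from 0.103 to 0.953) 12 of 226 members rose, among them EGR3 (0.88), the p53 target BBC3 (0.55) and the respiratory chain gene UQCRFS1 (0.24), and 19 fell, among them DDB2 (-0.39).

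**Figure D2:**
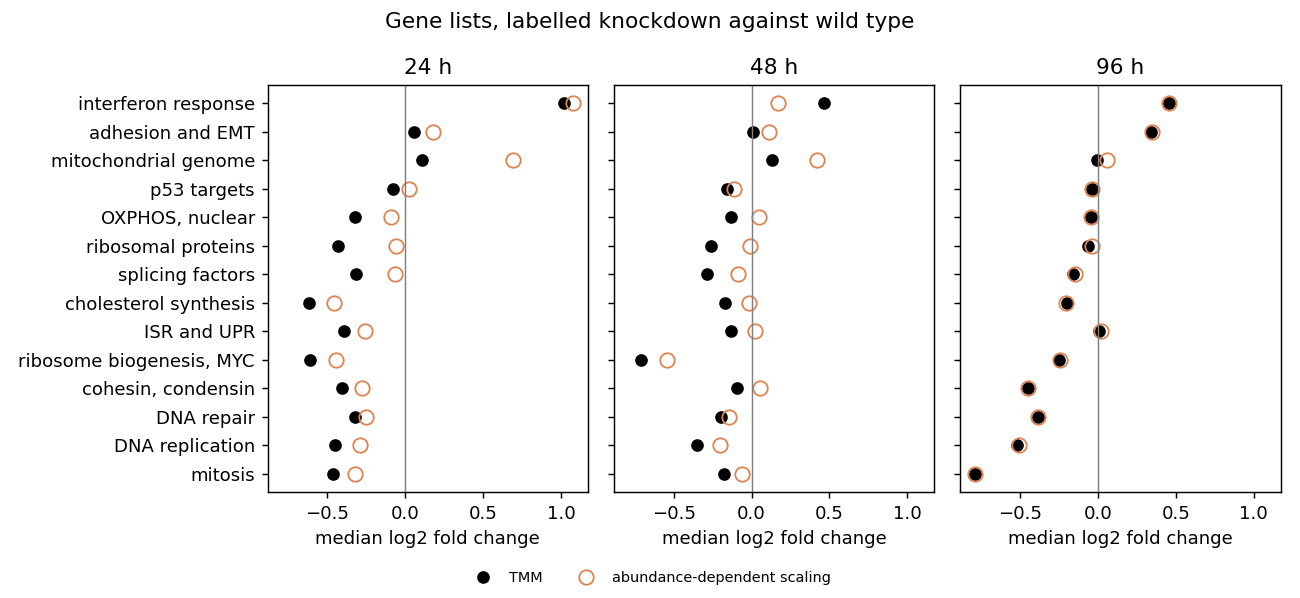
Median log2 fold change of knockdown against wild type at 24 h, 48 h and 96 h, for 14 gene lists, with filled points for TMM and open points for abundance-dependent scaling. The interferon median was 1.02 at 24 h and 0.46 at both later times, and the mitosis median was -0.46, -0.18 and -0.79 under TMM, and the respiratory chain median at 48 h changed sign, from -0.13 under TMM to 0.05.

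The retained-intron share at 96 h was 4.67% ± 0.188 (SD, n = 3) in knockdown and 4.54% ± 0.0781 (n = 3) in wild type, that of mitochondrially encoded genes was 14.42% to 16.88% in knockdown and 15.04% to 16.19% in wild type, and 51.0% of called genes rose under TMM and 50.2% to 54.4% under the other scalings. The count of 2083 genes fell to 1239 without wild-type replicate 2, 1269 without knockdown replicate 3 and 1334 without knockdown replicate 2 of 96 h, and was 3344 without knockdown replicates 1 and 2 of 48 h together. Calls ended for RCOR1 (edgeR adjusted p = 0.0701, 0.0765, 0.0811 and 0.0965 without knockdown replicates 1 and 2 and wild-type replicates 2 and 3), AL392023.2 (0.0626, 0.0628 and 0.0558 without knockdown replicates 1 and 2 and wild-type replicate 1), TDP1 (0.0908 and 0.0992 without knockdown and wild-type replicate 2) and ESRP1 (0.0915, 0.141, 0.0588 and 0.147 without knockdown replicates 2 and 3 and wild-type replicates 1 and 2). Of the 6 libraries of 96 h, PARP1 was lost without any but knockdown replicate 1, PDK1, ENO1 and BNIP3 without any but wild-type replicate 3, and UQCRFS1 without any but knockdown replicate 1 and wild-type replicate 2 (edgeR adjusted p up to 0.209, 0.152, 0.161, 0.194 and 0.157). All of them but PDK1 were lost without single libraries of 24 h or 48 h too (0.0503 to 0.0676). The hypoxia list was lost without replicate 1 or 2 of either group at 96 h (camera adjusted p = 0.0603 to 0.117). The ribosomal protein list was lost without knockdown replicates 1 and 3 and wild-type replicates 1 and 2 (0.0928 to 0.489).

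Averaged over the 3 times, 7125 genes passed, 2964 rising and 4161 falling, and ZNF10 (log2 fold change 7.61, SE 0.374, edgeR adjusted p = 6.81e-08) and CEMIP (3.92, SE 0.10, edgeR adjusted p = 2.25e-14) rose most. They were followed by ZNF608 (1.66), ITGAX (1.61), IFIT1 (1.57), IFI6 (1.56), CARNS1 (1.45), SPTSSB (1.32), ECM1 (1.28) and CENPT (1.28). The largest falls were of CEP83 (-2.68, SE 0.099, edgeR adjusted p = 4.31e-14), KCNK1 (-2.23), EPHB2 (-2.17), the homeobox gene TLX3 (-1.73), FKBP10 (-1.68), CYP24A1 (-1.33), MARC1 (-1.29), the antisense gene MGC32805 (-1.26), SCGB3A2 (-1.18) and AL392023.2 (-1.18). Over 48 h and 96 h alone, 6141 genes passed, 2657 rising and 3484 falling under TMM, 3697 rising and 2416 falling under total-count scaling, 3699 and 2564 under upper-quartile scaling, and 2899 and 2954 under abundance-dependent scaling. The share of called genes that rose in the average was 41.6% under TMM, 68.0% under total-count scaling and 60.05% under upper-quartile scaling.

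The same genes tended to move at the 3 times, which share no control library. Across 19836 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.279 between 24 h and 48 h, 0.190 between 24 h and 96 h and 0.164 between 48 h and 96 h (Spearman's rho 0.482, 0.330 and 0.269). Over the 11053 genes with a mean CPM of at least 5 it was 0.651, 0.588 and 0.507. Between 24 h and 48 h 670 rises were shared where independent lists would share 150.4, and 1836 falls against 455.2. Between 24 h and 96 h 423 rises (54.6) and 699 falls (126.9) were shared, and between 48 h and 96 h 536 rises (156.8) and 649 falls (188.5). At all 3 times 323 genes rose (8.1) and 550 fell (23.4).

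The size of the change differed between times for 1872 genes (edgeR test with 2 degrees of freedom). Among them were NORAD and the interferon-stimulated OAS1, which rose at 24 h (2.65) and fell at 48 h (-0.61; edgeR interaction adjusted p = 1.13e-06). Between 48 h and 96 h 2171 genes differed, 1337 more positive and 834 more negative at 96 h under TMM. Under total-count scaling it was 631 and 1484, under upper-quartile scaling 871 and 1275, and under abundance-dependent scaling 851 and 877. The count was 5252 without knockdown replicate 3, 1397 without knockdown replicate 1 and 1351 and 1386 without wild-type replicates 1 and 2 of 48 h, and 1268 without knockdown replicate 2 and 1354 without wild-type replicate 3 of 96 h. Mitosis genes were more negative at 96 h (median difference -0.57, camera adjusted p = 7.26e-25; adjusted p = 0.205 with an estimated correlation). Ribosome biogenesis genes were less so (0.53, camera adjusted p = 4.00e-15; adjusted p = 0.205 with an estimated correlation). The mean change at 48 h and 96 h differed from that at 24 h for 161 genes, 109 more positive and 52 more negative, and this division and count rested on single libraries and on the scaling. The count was 41 without wild-type replicate 1 (19 more positive), 96 without wild-type replicate 2 and 48 without knockdown replicate 2 (15 more positive) of 24 h. It was 96 without wild-type replicate 2 (47 more positive), 255 without knockdown replicate 1 and 415 without knockdown replicate 3 of 48 h, 868 without knockdown replicates 1 and 2 of 48 h together, and 104 without knockdown replicate 2 of 96 h. Under total-count scaling 51 were more positive and 108 more negative, under upper-quartile scaling 96 and 80, and under abundance-dependent scaling 93 and 87. DESeq2 gave 313 genes, and the replicate block within each time 101. The interferon list was less positive late (median difference -0.83, camera adjusted p = 6.21e-25; adjusted p = 1.69e-04 with an estimated correlation). The count of 1872 depended on single libraries: it was 5035 without knockdown replicate 3 of 48 h, 1052 without knockdown replicate 2 and 1150 without wild-type replicate 3 of 96 h, 1058 without wild-type replicate 2 and 1203 without wild-type replicate 1 of 48 h, and 1218 without knockdown replicate 2 and 1238 without wild-type replicate 1 of 24 h.

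**Figure D3:**
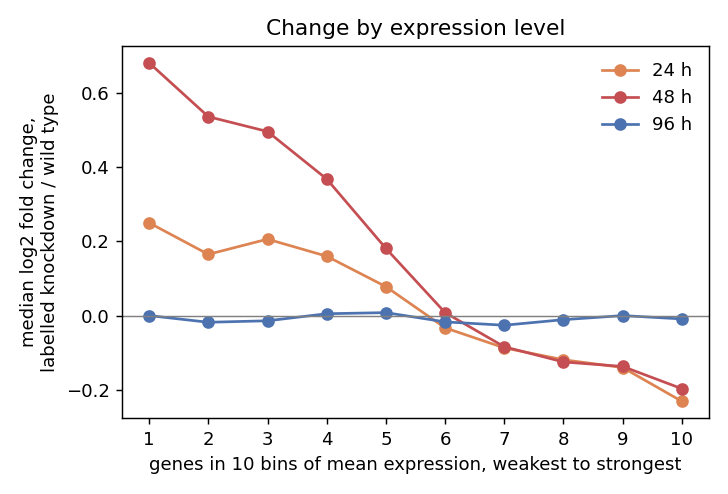
Median log2 fold change of knockdown against wild type in 10 bins of 1983 or 1984 genes from the lowest to the highest mean expression, as 1 line per time. The medians ran from 0.25 to -0.23 at 24 h and from 0.68 to -0.20 at 48 h, and lay between -0.03 and 0.01 at 96 h. On protein-coding transcripts alone, the gap between the end bins at 48 h was 0.913, 0.805 and 0.147 in knockdown replicates 1, 2 and 3.

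In wild-type cells alone, 6984 genes differed between 24 h and 96 h, 3204 higher and 3780 lower at 96 h (4490 without wild-type replicate 1 of 24 h), with 839 and 1055 of them at least doubled or at most at the inverse. The chemokine gene CXCL14 was at 0 in both 24 h libraries and at 304.7 ± 81.0 CPM at 96 h (SD, n = 3), at least 5476-fold higher against a floor of 3 counts over the group. KCNJ2 (0.0742 to 563.0 CPM), NEDD9 (0.426 to 1569 CPM), NEUROD2 (0.261 to 206.0 CPM) and PSG2 (0.0371 to 37.7 CPM, on 2 reads at 24 h) rose as well. In these 5 genes 99.95% to 100% of the counts were in transcripts that hold a run of at least 31 A or T. NEDD9 outside those transcripts had a log2 change of -1.24 (edgeR adjusted p = 0.204). The other way, MARCH11 went from 55.4 ± 23.0 CPM (n = 2) to 0, at least 2570-fold lower, AC008738.5 from 51.99 CPM to 0, at least 2413-fold lower. HIST2H2AA3 went from 17.0 CPM to 0, at least 790.1-fold lower, RNU2-4P from 113.2 to 0.00801 CPM, on 1 read at 96 h, and IL32 from 508.6 ± 341.8 to 0.156 ± 0.0829 CPM. Transcripts with such a run held 0.555% to 0.672% of the counts at 24 h, 4.11% to 6.42% at 48 h and 2.26% to 4.44% at 96 h over both genotypes.

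NORAD binds the Pumilio proteins, repressors that recognise UGUANAUA in 3' UTRs, and the genes with that motif were close to the others. The 3811 tested genes with the motif differed from 11347 without it by a mean log2 fold change of -0.03 at 24 h, -0.04 at 48 h and -0.05 at 96 h (unadjusted camera p-values 0.922, 0.604 and 0.0361, adjusted over the 3 times 0.922, 0.906 and 0.108). With at least 2 motifs the difference at 96 h was -0.06 (camera adjusted p = 0.0247), and with 3' UTR length and GC content as covariates it was 0.00 (camera adjusted p = 0.893). The reversed word, chosen as a control after the result was seen, differed by -0.06 (camera adjusted p = 0.0287). The 96 h difference over genes with at least 1 motif passed without knockdown replicate 1 (-0.08, camera adjusted p = 0.00603) or wild-type replicate 1 (-0.06, camera adjusted p = 0.034) of 96 h. Of 13 single genes known as Pumilio-repressed, ATXN1 rose at each time (0.44, 0.44 and 0.39). The cell cycle genes CCNB1, MAD2L1 (-0.65, -0.56 and -0.83) and BUB1B (-0.51, -0.41 and -0.86) fell at each time. SMC1A fell at 24 h (-0.38) and 96 h (-0.43), the cohesin acetyltransferase gene ESCO2 at 48 h (-0.29) and 96 h (-0.68) and E2F3 at 48 h (-0.51; adjusted over the list alone 5 fell at 24 h, 6 at 48 h and 5 at 96 h). SMC1A, ATXN1 at 96 h and BUB1B at 48 h were named after their values were seen. The list passed at 96 h (camera adjusted p = 0.00186; adjusted p = 0.500 with an estimated correlation) and not at 24 h or 48 h (camera adjusted p = 0.236 and 0.105). The 5 that fell at 96 h were the cell cycle genes, SMC1A and ESCO2. This pass cannot be told apart from the fall of mitosis genes. Of the 9 Pumilio and partner genes the deadenylase subunit gene CNOT7 fell at each time (-0.39, -0.46 and -0.28) and CNOT6 at 48 h (-0.25; adjusted over the list alone 1 fell at each time). That list passed at 96 h (camera adjusted p = 0.0362; adjusted p = 0.465 with an estimated correlation) and not at 24 h or 48 h (camera adjusted p = 0.206 and 0.0771).

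Several of these single-gene calls ended under another scaling or when 1 library was left out. Under total-count, upper-quartile and abundance-dependent scaling SMC1A at 24 h (edgeR adjusted p = 0.396, 0.104 and 0.199), ESCO2 at 48 h (0.21, 0.106 and 0.0584) and CNOT6 at 48 h (0.332, 0.196 and 0.282) did not pass. ESCO2 and CNOT6 did not pass with only the libraries of 48 h in the fit either (0.0552 and 0.108). CNOT7 at 24 h was lost under total-count and abundance-dependent scaling (0.168 and 0.0921), and BUB1B at 24 h under total-count scaling (0.0682). With 1 library left out, the calls at 24 h ended for ATXN1 without knockdown replicate 1 (edgeR adjusted p = 0.0892), MAD2L1 (0.0605 and 0.0603), BUB1B (0.0839 and 0.0662) and CNOT7 (0.108 and 0.126) without wild-type or knockdown replicate 2, and SMC1A without any of 12 of the 16 libraries (0.0523 to 0.332), that is, all but knockdown replicates 2 and 3 of 48 h and 1 and 3 of 96 h. At 48 h it held for ESCO2 without replicate 1 or 2 of either group (0.0781 to 0.112) and for CNOT6 without any library of 48 h but knockdown replicate 3 (0.0761 to 0.162) and without 6 libraries of 24 h and 96 h (0.0506 to 0.0565). Without knockdown replicates 1 and 2 of 48 h together MAD2L1 (0.0918), BUB1B (0.285), ESCO2 (0.563) and CNOT6 (0.78) did not pass there. Without knockdown replicate 3 of 48 h the list of Pumilio-repressed genes passed at 48 h (camera adjusted p = 0.0144). At 96 h it held for CNOT7 without wild-type replicate 2 and knockdown replicates 2 and 3 (0.154, 0.101 and 0.124) and SMC1A without knockdown replicate 3 (0.0689). The Pumilio and partner list was lost without the same libraries as CNOT7 (camera adjusted p = 0.15, 0.0769 and 0.0554).

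Among the 11 tested genes next to NORAD on chromosome 20, DLGAP4 rose (0.44) and RBM12 fell (-0.50) at 48 h, and SCAND1 rose (0.40) at 96 h. The list passed at no time by camera (camera adjusted p = 0.301, 0.553 and 0.247; 1 rose and 1 fell at 48 h and 2 rose at 96 h adjusted over the list alone). At 24 h the 9 further lists without a call (camera adjusted p from 0.105 to 0.974) held 137 tested members, of which 11 rose, among them the p53 target TP53I3 (0.63), and 16 fell, among them the p53 target GDF15 (-0.82). For lists that passed at no time by camera under TMM, the camera adjusted p at 24 h, 48 h and 96 h was 0.882, 0.136 and 0.657 for beta-catenin targets, whose median (0.08) and mean (-0.15) differed in sign at 24 h, 0.791, 0.243 and 0.553 for intestinal differentiation. It was 0.731, 0.645 and 0.204 for NF-kappaB targets, 0.105, 0.159 and 0.953 for mitochondrially encoded RNAs (8.37e-14 at 24 h and 2.09e-06 at 48 h, upward, under abundance-dependent scaling, and 0.01 at 48 h without knockdown replicate 1 of 48 h) and 0.974, 0.746 and 0.611 for other abundant lncRNAs. Markers of other cells that a culture could hold did not pass by camera either, with 0.379, 0.701 and 0.701 for the erythroleukaemia line K562 and 0.657, 0.336 and 0.746 for fibroblasts, of which the collagen gene COL1A1 rose at 48 h (1.07). The list of embryonic kidney cell markers had only 3 tested members and was not tested.

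Transcript usage within genes was compared because alternative splicing is part of the stated purpose. All counts in the tested transcripts of IL23R (ENSG00000162594, chr1:67138907-67259979, plus strand, GRCh38), at a mean of 2.23 CPM, were outside ENST00000347310 in wild type and within it in knockdown. This held at 24 h, 48 h and 96 h (limma adjusted p = 2.88e-05, 9.35e-07 and 3.40e-05). NORAD was not lower at 24 h, so the IL23R difference did not follow the NORAD level. RIC8A (chr11:207511-215113, plus strand) had 51.5% ± 1.76 of its counts in ENST00000325207 in wild type and 18.3% ± 1.22 in knockdown at 48 h (n = 3 and 3, limma adjusted p = 2.64e-05). A limma test of the share of each transcript, added after the planned test did poorly on simulated data, called 57 genes at 24 h, 47 at 48 h, 9 at 96 h and 64 in the average of 10258. Between 24 h and 48 h 7 were shared (0.26 for independent lists).

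The planned edgeR diffSpliceDGE test of 12784 genes called 199 genes at 24 h, 520 at 48 h, 195 at 96 h and 449 in the average, with Simes p-values and Benjamini-Hochberg adjustment. On simulated counts 48.8%, 61.4%, 63.8% and 58.4% of its calls were false, against 8.53%, 9.52%, 8.73% and 4.32% for the share test. Genes with its lowest p-values were MRPL42, RPSA, FANCA and DDX39A at 24 h (edgeR adjusted p from 4.02e-09 to 1.14e-07), RPS2, MYO1C, MROH1 and IL4R at 48 h (1.19e-23 to 6.74e-10), PKM, TYK2, PTPRF, TRAF4 and PSMF1 at 96 h (3.46e-37 to 1.04e-08) and RPS2, RPSA, TYK2 and DDX39A in the average (3.61e-22 to 7.12e-11). Many of these rest on minor transcripts: ENST00000389093 of the pyruvate kinase gene PKM held 0% of its gene in wild type and 1.39% ± 0.605 in knockdown at 96 h (SD, n = 3 and 3). Between times 24 genes were shared at 24 h and 48 h (8.1 for independent lists), 14 at 24 h and 96 h (3.0) and 30 at 48 h and 96 h (7.9).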

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

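All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the libraries, which were planned. The knockdown effect differed between 24 h, 48 h and 96 h for 1872 genes. It did so for 70 of 142 named genes, by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment. Of 100 splits of the libraries within their times, 6 gave as many genes, the real split included, and the highest other gave 7118. In each of the 5 others the groups of 24 h and of 48 h stayed whole, and in 4 of them the groups were exchanged at 1 of these times. An exchange at 1 time turns an effect shared by the times into a difference between them, so these splits do not test chance for this count, which stays open. For the average over the times the real split was the only one of 100 to reach its count (7125 genes, highest other 4859). This argues against a random division of these libraries. It cannot exclude chance differences between cultures, because the labels do not say that replicates came from separate cultures. At 48 h and 96 h the 10 possible splits are too few for a share under 0.05. The real split, 1 of 10 at each time, gave 6591 and 2083 genes and the highest other 548 and 1. For transcript usage the same holds, with 520 genes at 48 h (2 of the 10 splits gave as many; highest other 1327, with wild-type replicates 1 and 2 and knockdown replicate 3 together, which points to a structure of the samples) and 195 at 96 h (highest other 171).

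Besides NORAD (edgeR interaction adjusted p = 8.28e-10), the genes singled out by that test are given with its adjusted p. The estimate was above 0 at each time and furthest from 0 at 24 h for IFIT1 (2.80e-05), IFI6 (1.15e-06), ZNF608 (3.64e-04), PARP10 (0.00533), IFIT3 (2.82e-04), STAT2 (0.0386) and OASL (0.00464). At 48 h it was so for TP53I3 (0.0157), ITGAX (7.54e-04), SPTSSB (5.89e-04), TRIML2 (5.57e-06), CENPT (1.91e-04), IRF7 (2.75e-04) and COL1A1 (3.69e-04), and at 96 h for GALNT5 (0.0019) and CLDN3 (0.0325). It was below 0 at each time and furthest from 0 at 24 h for CEP83 (1.11e-05), KCNK1 (8.28e-10), EPHB2 (6.74e-09), FKBP10 (6.14e-08), PLEKHH2 (3.05e-04), XAB2 (0.0454), FBL (0.00485), TCOF1 (0.0303), INSIG1 (0.026), FDPS (0.0225), ACAT2 (0.00903), ASNS (0.00464), TOP1 (0.0147), RPL14 (0.0374), NDUFA10 (0.0118), GDF15 (0.0189) and TLX3 (1.54e-05). At 48 h this was so for MYC (5.28e-04), CYP24A1 (2.92e-08), CPA4 (5.97e-08), KRT13 (2.82e-04), WNT16 (1.84e-04), RRS1 (1.40e-04), NCL (0.00341), TRIAP1 (0.00615), PTP4A1 (0.00385), SDHD (0.0393) and MGC32805 (0.024), and at 96 h for UBE2C (0.00217), CCNB1 (0.0145), AURKB (0.00109), NCAPG (2.99e-04), HMMR (0.00134), FAM72D (0.0463), CENPF (7.65e-05), POLA1 (0.0214), FANCD2 (0.0115) and SGO2 (0.00505). Estimates whose sign was not the same at the 3 times are given as log2 fold changes at 24 h, 48 h and 96 h before the adjusted p: OAS1 (2.65, -0.61 and 0.57; 1.13e-06), DDX58 (2.03, -0.15 and 0.70; 0.0334), CHAC1 (-1.01, 0.32 and 0.14; 0.0012), TOP2A (-0.41, 0.07 and -0.98; 2.48e-05), HIST1H4C (-0.93, 0.50 and -1.15; 0.00673), KIDINS220 (1.74, -2.27 and 0.64; 0.0325) and EGR1 (-0.23, 1.18 and 0.41; 2.50e-05). The others were KRT20 (-0.04, -1.73 and 0.02; 2.41e-05), CDX2 (-0.26, -0.51 and 0.01; 0.0452), CDC25C (-0.29, 0.48 and -0.40; 0.00166), CENPE (-0.42, 0.35 and -0.92; 3.05e-04), CDKN1A (-0.06, 0.41 and 0.16; 0.0463), MDC1 (-0.42, 0.06 and -1.06; 0.0102), CLDN4 (-0.19, -0.21 and 0.57; 3.34e-04) and BBC3 (-0.16, -0.01 and 0.55; 0.00161). Among the fixed lists, the interferon-stimulated genes changed less at the later times than at 24 h with an estimated correlation too (camera adjusted p = 1.69e-04).

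The first pattern is that genes differed at 24 h although NORAD did not pass, and an exchange of the labels is argued against by ZNF10, whose lowest CPM in the 24 h knockdown libraries was 179.4 times the highest in the 24 h wild-type libraries. A candidate explanation is a standing difference between the knockdown and wild-type cells that does not follow the NORAD level, such as the CRISPR machinery or clonal differences. Of the genes called at 24 h, 87.2% had the same sign at 96 h and 93.4% at 48 h, against 50.5% by chance, and the median change in the 24 h direction at 96 h was 0.21 log2 against a median size of 0.47 at 24 h. The ZNF10 reads may come from a KRAB domain carried by the repressor. In the 8 knockdown libraries 12301 of 12335 (99.72%) lay in 1 transcript, and in wild type 35 of 47 (74.47%). This argues against an even rise of the gene's transcripts. Since 99.99% and all 47 lay in transcripts without the zinc-finger exon, that exon does not tell repressor from gene. An early effect of the induction and an effect of doxycycline stay open, as untested.

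The second pattern is that at 24 h and 48 h weakly expressed genes were higher and strongly expressed genes lower in the knockdown libraries, by a gap between the lowest and highest of 10 expression bins of 0.481 and 0.878 log2. The loss of NORAD as the whole cause is argued against by the gap of 0.009 at 96 h, when NORAD was at 39.9% of wild type, and by the gap at 24 h, when it was not lower. More reads from unspliced RNA may account for the gap. Over the 8 knockdown libraries the gap per library, on protein-coding transcripts, rose with the excess of retained-intron counts over wild type. Spearman's rho was 0.881 (exact permutation p = 0.00724) and Pearson's r 0.961 (exact permutation p = 0.000273), both two-sided over 40320 permutations. Without the 2 farthest libraries r was 0.897. The libraries come from 3 times, with 2 or 3 per time, too few for a value within a time. Only counts of annotated transcripts were seen, so unspliced RNA itself was not shown. Counts of antisense genes were higher too in knockdown replicates 1 and 2 of 48 h (0.531% and 0.557%). They were 0.373% in knockdown replicate 3 and 0.369% to 0.393% in wild type of 48 h. What these reads are, and whether they came from the handling of these libraries or from the cells, stays open.

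The third pattern is that a set of genes was read strongly in the 48 h and 96 h libraries and barely at 24 h. Reads made of a run of A or T and assigned to transcripts that hold such a run may account for part of it: 18 of the 42 genes at least 32-fold higher in wild type at 96 h than at 24 h (42.86%) held such a transcript, against 0.581% of the other tested genes (Fisher's exact p = 7.02e-29, two-sided). At 96 h in wild type the genes with a run lay between 8.32 (HEPACAM) and 1998 CPM (FGF23). Those without lay at 1.13 CPM (ARHGEF19-AS1) or less, except CLDN11 (14.9 CPM) and TENM3 (8.49 CPM). Most of the strongly read genes therefore held a run, and 42.86% understates their share. For the 18 genes with a run, a rise with time in culture cannot be told apart from such reads. Only 4 of the 18 had counts outside transcripts with a run (median log2 change 0.18, from -1.24 to 1.00). Time and library batch are confounded for the other genes, and no biological explanation was tested.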

How the results depend on the processing

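Alternatives chosen after the data were seen were total-count, upper-quartile and abundance-dependent scaling, leaving out transcripts with runs of A or T, leaving out knockdown replicates 1 and 2 of 48 h together, the mean of 48 h and 96 h alone, length and GC covariates together, the reversed motif and the share test of usage. The tests under the others were planned. Of 486 alternative values of the 22 main results, 425 kept their direction and side of the threshold or stayed within 1.5 times, 57 moved further and 4 passed where the reported value did not. Of 1680 alternative list tests, 1593 kept their call, 64 lost it, 19 gained it and 4 turned direction. Of 6535 for named genes, 6057 kept it, 477 lost it and 1 turned. Of 220 for each setting, DESeq2 ended 0, limma-voom 4, RLE factors 9, no filter 16 and the scalings 17 to 22 (14 of 219 with CPM of at least 5, 19 of 190 with only the libraries of that time). Where a value changed, the cause was not tested, except that a minimum fold leaves fewer calls by construction. Every setting fixed in advance was run. Depth limits genes at a few counts.

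glmTreat against a 1.2-fold change called 1018 genes at 24 h, 2634 at 48 h and 444 at 96 h, and the transcript-level test gave 1030, 3114 and 400 genes with a called transcript. With only the libraries of that time, 4072 genes passed at 48 h and 3450 at 96 h. Without knockdown replicates 1 and 2 of 48 h together, 3990 passed at 48 h and 3344 at 96 h. DESeq2 gave 2846 genes that differed between times. With single libraries left out, counts ranged from 1500 to 4558 at 24 h, 1239 to 3069 at 96 h, 1052 to 5035 for the difference between times and 4490 to 8276 for wild type over time, and usage counts from 129 to 243, 330 to 1201, 112 to 221 and, in the average, 267 to 840. A group left with 1 library is then assumed to vary like the other groups. NORAD at 24 h passed as higher under total-count scaling (log2 fold change 0.341). Over genes with a mean CPM of at least 5, r between times was 0.651, 0.588 and 0.507.

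With an estimated correlation, camera passed 1 list at 24 h, 0 at 48 h and 2 at 96 h, against 16, 11 and 14 with the preset correlation (8, 2 and 7 lists had an unadjusted p under 0.05 with the estimated correlation, and fry passed 16, 16 and 12), and under abundance-dependent scaling 7 at 48 h. The ribosomal protein and respiratory chain lists turned direction at 48 h under that scaling (camera adjusted p = 0.936 and 0.678), the hypoxia list at 24 h without knockdown replicate 2 (camera adjusted p from 3.27e-10 to 0.99 with libraries left out), and the beta-catenin list at 24 h under fry (0.0295). Calls gained were EMT and adhesion at 24 h (0.0224 under abundance-dependent scaling, 0.0402 without knockdown replicate 2) and immediate early genes at 48 h (0.00915 under that scaling). Under fry, which compares a list with no other genes, NORAD neighbours passed at 24 h (0.0402), and at 48 h Pumilio and partners (0.02), topoisomerases (0.00113), beta-catenin targets (5.72e-04), intestinal differentiation (9.90e-04) and fibroblast markers (0.0233). Stress responses (0.0107) and histones (0.0109) passed at 48 h without knockdown replicates 3 and 1 of 48 h. Histones passed at 96 h without replicate 3 of 48 h (0.0256). NEDD9 over time in wild type turned to -1.237 without transcripts with runs. The Pumilio motif difference at 96 h passed with at least 2 motifs (-0.059) and ranged from -0.076 to -0.033 with libraries left out. Usage counts were 79, 81, 29 and 102 at 24 h, 48 h, 96 h and in the average for transcripts with at least 10% of the gene, 54, 1431 and 677 at 24 h, 48 h and in the average by limma diffSplice, and 57, 47, 9 and 64 by the share test.

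The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.08 at 24 h, -0.177, -0.268 and -0.235 at 48 h and -0.488, -0.212 and 0.107 at 96 h. With the number as a block within each time, 2587, 5227, 1437 and 6245 genes passed at 24 h, 48 h, 96 h and in the average, 900 differed between times, and usage counts were 49, 179, 73 and 127; every list kept its call and 40 of 440 values of named genes lost theirs over both block fits.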

Other observations

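Tests here on ZNF10 and on chromosomes were chosen after the results were seen. Of the ZNF10 counts of the knockdown libraries, 99.72% were in ENST00000536877 (35 of 47 reads, 74.47%, in wild type), a transcript of 5 exons and 472 bases at chr12:133130611-133151866 (plus strand, GRCh38). The zinc-finger exon is held by 3 of the gene's 10 annotated transcripts. The difference of the ZNF10 effect between times did not pass (edgeR interaction adjusted p = 0.881).

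Few genes moved in opposite directions at different times. Between 24 h and 48 h 32 genes passed in opposite directions where independent lists would give 552, between 24 h and 96 h 19 (184.4), and between 48 h and 96 h 83 (346.8). No chromosome stood far from the rest: the median log2 fold change of a chromosome minus that of all genes lay between -0.09 and 0.07 over the 3 times, and on chromosome 20, which holds NORAD, it was 0.01, 0.00 and 0.01 at 24 h, 48 h and 96 h.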
